A study of Mus musculus with 2 samples.

How the data were processed

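Total RNA was extracted from sciatic nerves of mice at postnatal day 7 with Trizol, and libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. There was 1 library from control and 1 from Tsc1cKO nerve, and grouping followed the genotype given in the labels. The deposited values are FPKM (mapped fragments scaled by transcript length and library total) per gene, 1 table per library, per the file headers. CASAVA, TopHat, Cufflinks and the mouse build mm9 are named, without versions, per the submitters' processing notes. The role of each tool, the annotation and the library total used for scaling are not given in the sources used here. No use of strand was stated, so genes with overlapping spans are reported as uncertain, as are near-identical paralogs such as the globin genes.

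FPKM are not counts, and read depth was unknown. Among the 626 genes below 0.05 FPKM in both libraries and above 0, the most common ratio of Tsc1cKO to control was 0.901, which reflects relative depth only if these genes hold equal fragment numbers in both libraries. The FPKM summed to 416853 in control and 492760 in Tsc1cKO, and 5928 and 5839 gene entries were at 0. The 10 highest genes held 12.5% of the sum in control and 6.39% in Tsc1cKO.

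Each table held 22532 entries, and 227 symbols stood on more than 1 entry (663 entries) and were summed, giving 22096 symbols. The tables carry a status per value. This column was examined after the files were seen, and 3 genes with a failed estimate in 1 library were left out, leaving 22093. Genes with at least 1 FPKM in 1 library or both, 12409 in number, were called measured. Differences were taken as log2(FPKM + 1) in Tsc1cKO minus that in control, with a pseudocount of 1. With 1 library per group no test of genotype, p-value or standard error was possible, so genes were counted by a rule of size, a difference of at least 1 on the log2 scale in either direction, which corresponds to 2-fold.

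Gene lists, 39 in number with 745 entries, were compiled from general knowledge of Schwann cell and nerve biology, and 7 entries matched no usable gene. They covered the TSC complex, polo-like kinases, myelin, myelination factors, Schwann lineage, immature and repair Schwann cells, node and adhesion, cholesterol and fatty acid synthesis, cell cycle, signalling, metabolism, stress and cell type markers. The median difference of each list with at least 5 measured members (36 lists) was set against 10000 random lists of the same size, drawn from measured genes in 20 bins of mean log2(FPKM + 1). A list outside the central 95% of random medians was described as above or below its random range, which describes these libraries only. Of the 36 lists, 12 lay above and 11 below.

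Genes named in the text were Tsc1, Tsc2 and Plk1 to Plk5, then the 10 largest positive and 10 largest negative differences among genes with at least 5 FPKM in 1 library or both and above 0 in both, leaving out small RNAs, predicted genes and pseudogenes. For each list, up to 4 members with the largest absolute difference could be named, and for the main lists also the member with the highest mean FPKM. Some genes that meet this rule are not reported here. Genes outside this rule are said to have been chosen after their values were seen, apart from Mbp and Hmgcs1, which are named for a share of the FPKM sum and for a value of 0. The lists, the rule for named genes, the thresholds and the other settings were fixed before the data were examined.

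The counting rule and list comparison were tested on simulated data made from the 12409 measured genes of the control library with noise of SD 0.3 on the log2 scale. All 200 genes changed by 4-fold were recovered and 8 of 12209 unchanged genes passed 2-fold. Of 100 unshifted lists 8 lay outside the random range, and of 50 lists of 20 genes shifted by 0.5 all 50 lay above it. The noise was an assumed value, independent between genes, without a shift or a length trend, and the 4-fold genes had at least 5 FPKM in control. The real differences had an SD of 0.62. The simulation therefore checks the calculation and gives no error rate for these libraries.

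Other settings fixed in advance were pseudocounts of 0.1 and 5, no filter or a filter of 5 FPKM, scaling by the median ratio (factor 1.18), the upper quartile (1.14) or a trimmed mean (1.17, with 30% of ratios and 5% of levels trimmed), removal of small RNAs, predicted genes and pseudogenes, removal of symbols on more than 1 entry, thresholds of 1.5-fold and 3-fold, list means, unmatched random lists, lists without the member with the largest difference and lists without genes shared with another list. Settings chosen after seeing the data were centring within 10 classes of transcript length and keeping failed values as listed. Lengths were medians over protein-coding transcripts per symbol in GENCODE M21, an annotation of another mouse build, so only lengths and no coordinates were taken from it. Lengths were found for 12036 measured genes (97.0%).

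Coordinates are those of the files in mm9. Starts were treated as counted from 0 and raised by 1, because end minus start equalled the annotated length for 595 of 626 matched microRNA genes. Calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.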

Results

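Gene expression was measured by RNA sequencing in sciatic nerves of mice at postnatal day 7. One nerve library came from a control and 1 from Tsc1cKO animals, read here as a conditional knockout of Tsc1, which encodes a subunit of the TSC complex that restrains the growth-promoting kinase complex mTORC1. The labels used here name neither the cells in which Tsc1 was deleted nor the number of animals behind a library. They give the control genotype only as control, so it is not known here whether those animals carried a deleted copy of Tsc1, which would change what each difference measures. Whole nerve contains Schwann cells, which build the myelin sheath around axons, together with fibroblasts, vessels, immune cells and perineurial cells, and each value covers all of them. The 2 libraries covered the same 22532 gene entries, of which 11950 genes reached 1 FPKM (mapped fragments scaled by transcript length and library total) in control and 12118 in Tsc1cKO. The sequencing depth was unknown. There were no replicates, so no difference has a replicate check, and "higher" and "lower" describe these 2 libraries and not the genotypes. Pairs of FPKM values are given with control first, and differences are Tsc1cKO minus control on the log2(FPKM + 1) scale, which understates the change of genes with low values. Values of Tsc2, Pmel, Sox2, Ccnd3, Ddit3, Tm7sf2, Runx2, Nhp2, Pfkp, Lgi4 and Tagln are uncertain, because each gene span overlaps that of a neighbour.

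The comparison addressed how the nerve transcriptome differs without Tsc1, with the polo-like kinases as the gene family of interest. Tsc1 itself, on chromosome 2, 28496763 to 28546687 (mm9), was at 3.76 and 2.28 FPKM, a difference of −0.53 and 1.64-fold lower in Tsc1cKO. This value spans the whole gene and all cells of the nerve, so it does not isolate deleted exons. Tbc1d7 and Tsc2, which encode the other members of the complex, were also lower, at 20.98 and 14.3 FPKM for Tbc1d7 and 16.2 and 14.2 FPKM for Tsc2. The median difference of the 3 genes was −0.53.

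All 5 polo-like kinase genes had higher values in Tsc1cKO. Plk2 (chromosome 13, 111185252 to 111191051), which encodes a kinase induced by growth factors and stress, was at 27.4 and 124 FPKM, 4.53-fold higher. Plk1 (chromosome 7, 129302951 to 129313389), whose product drives entry into and passage through mitosis, was at 5.52 and 12.1 FPKM, 2.20-fold higher. Plk4, which encodes the kinase that starts centriole duplication, was at 2.87 and 4.61 FPKM, and Plk3 at 2.15 and 2.94 FPKM. Plk5 was low in both libraries, at 0.149 and 1.01 FPKM. The median difference of the family was 0.80, against −0.37 to 0.63 for the central 95% of 10000 random lists of the same size and expression level. This median is the value of Plk5, which reached 1 FPKM only in Tsc1cKO. After median, upper quartile or trimmed mean scaling Plk5 fell below 1 FPKM in both libraries, and the list had too few members to compare. The differences of Plk1 and Plk2 were 1.01 and 2.14 as deposited and 0.79 and 1.91 after the median scaling described next, so Plk1 passed 2-fold on this scale only without scaling. The median of the family lay inside the random range with a pseudocount of 5.

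Across the 12409 genes with at least 1 FPKM in 1 library or both, 624 were at least 2-fold higher in Tsc1cKO and 380 at least 2-fold lower. The median difference of all these genes was 0.20. Rescaling Tsc1cKO so that the median log2 ratio of the 7844 genes with at least 5 FPKM in both libraries was 0 removed a shift of 0.24 and gave 355 genes higher and 577 lower. The share of higher genes among those past 2-fold was thus 62.2% as deposited and 38.1% after scaling, and differences after this scaling are called centred below. Random ranges are given for the values as deposited. The shift went with a difference in composition, since Pmp22 and Mbp, which encode abundant myelin proteins, held 7.22% of the FPKM sum in control and 0.984% in Tsc1cKO.

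The genes with the largest positive differences included Tyrp1, which encodes a melanosome enzyme, at 0.361 and 802 FPKM (chromosome 4, 80480134 to 80497622), and Gpnmb, which encodes a glycoprotein of melanosomes and lysosomes, at 0.347 and 122 FPKM (chromosome 6, 48986517 to 49008181). They were followed by Pmel, which encodes the fibril protein of melanosomes, at 8.95 and 354 FPKM (chromosome 10, 128143314 to 128157294). Syt4, encoding a synaptotagmin, was at 1.17 and 55.9 FPKM, Ucn2, encoding the peptide urocortin 2, at 0.845 and 36.4 FPKM, and Lgals3, encoding galectin-3, at 8.86 and 199 FPKM. The chemokine gene Cxcl14 was at 5.31 and 91.0 FPKM, the bile acid receptor gene Nr1h4 at 0.304 and 15.7 FPKM and the dual oxidase maturation gene Duoxa1 at 0.542 and 18.4 FPKM. Differences of Tyrp1, Gpnmb and Pmel were 9.20, 6.51 and 5.16, and 8.97, 6.28 and 4.92 when centred.

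The largest negative differences were those of Col23a1, a transmembrane collagen gene, at 34.4 and 1.44 FPKM (chromosome 11, 51103422 to 51397427), and Drp2, whose product forms a complex with periaxin at the Schwann cell surface, at 137 and 9.61 FPKM (chromosome X, 130939319 to 130991112). Fam178b was at 307 and 27.1 FPKM, Vat1l at 251 and 22.7 FPKM and Sema5a, encoding a semaphorin, at 41.8 and 3.15 FPKM. Scn3b, encoding a sodium channel beta subunit, was at 35.1 and 2.93 FPKM, and the sulfotransferase gene Chst2 was at 35.7 and 3.24 FPKM. Spnb1, encoding a beta spectrin, was at 25.1 and 2.11 FPKM, the adenylyl cyclase gene Adcy1 at 24.7 and 2.13 FPKM and Ddn at 168 and 20.04 FPKM. Differences of Col23a1 and Drp2 were −3.86 and −3.70, and −3.99 and −3.91 when centred. The 19 genes listed at 0 in one library and at 5 FPKM or more in the other were all small RNAs or predicted genes and are not named.

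**Figure D1:**
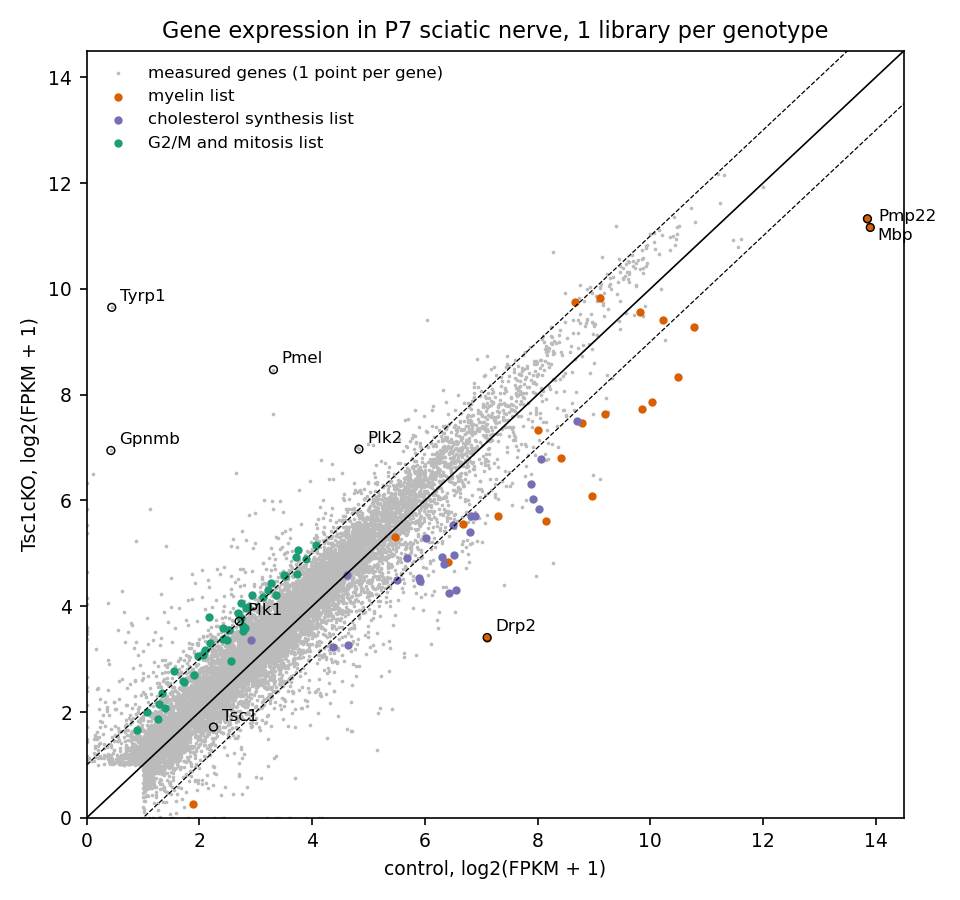
Expression of 12409 genes in control (horizontal axis) and Tsc1cKO (vertical axis) sciatic nerve as log2(FPKM + 1), 1 grey point per gene, with myelin, cholesterol synthesis and G2/M genes in colour, named genes circled, the solid line at equal values and dashed lines at a 2-fold difference. Tyrp1, Gpnmb and Pmel lie far above the lines, while Pmp22 and Mbp lie at the right edge at 15306 and 2287 FPKM and 14783 and 2564 FPKM.

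Myelin genes were lower in Tsc1cKO. Of 22 measured genes for myelin structure and maintenance, 20 were lower, 16 of them by at least 2-fold, and the median difference was −1.58 (−1.79 centred), below the random range of 0.11 to 0.63. Pmp22, which encodes a membrane protein of compact myelin, was at 15306 and 2287 FPKM, 6.69-fold lower (chromosome 11, 62945012 to 62973048). Ugt8a and Fa2h, whose products make the galactolipids of myelin, were at 498 and 67.2 FPKM and 282 and 47.8 FPKM, and Drp2 belonged to the same list.

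The transcription factors of myelination went both ways. Egr2, the master regulator of myelin genes, was at 67.9 and 32.7 FPKM and its co-factor gene Nab1 at 12.6 and 4.33 FPKM, whereas Pou3f1, which encodes the factor of the promyelinating stage, was at 78.8 and 269 FPKM. Tcf7l2 was at 8.07 and 4.93 FPKM. Sox10, the Schwann lineage factor, was at 212 and 246 FPKM, a difference of 0.21 that turned to −0.02 when centred. The list of 15 factors had a median of 0.06 and a mean of −0.02, and its median turned to −0.16 when centred. The 15 genes of the Schwann lineage, listed as not tied to the myelinating state, had a median of 0.21, which also turned to −0.02 when centred, with 9 of them higher as deposited and 7 when centred. Among them Foxd3 (53.9 and 144 FPKM), Cdh19 (23.3 and 55.9 FPKM) and Lgi4 (42.8 and 89.4 FPKM) were higher, and Cmtm5 (234 and 88.9 FPKM) and Plekha4 (397 and 208 FPKM) were lower. Neither median lay outside its random range of −0.04 to 0.50 or −0.03 to 0.59.

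Genes of the node, the paranode and adhesion between axon and glia were mostly lower, 19 of 21 as deposited, with 7 by at least 2-fold. The median was −0.59 (−0.80 centred), below the random range of 0.02 to 0.52. Cadm3, encoding a nectin-like adhesion protein, was at 75.2 and 13.9 FPKM, Nfasc, encoding neurofascin, at 40.6 and 8.24 FPKM and Cntn1, encoding contactin-1, at 5.53 and 1.04 FPKM. Cadm4, which encodes an adhesion protein of Schwann cells that binds axonal partners, was at 706 and 603 FPKM. Its relative Cadm1 was 3.65-fold higher, at 17.3 and 63.0 FPKM.

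Genes of lipid synthesis were lower together with the myelin genes. Of 23 genes for cholesterol synthesis and uptake, 22 were lower, 18 by at least 2-fold, with a median of −1.36 (−1.59 centred) against a random range of 0.04 to 0.52. Lss was at 93.0 and 18.8 FPKM, Tm7sf2 at 85.0 and 18.0 FPKM and Fdps at 416 and 179 FPKM, all coding for enzymes of the same pathway. Hmgcs1, another enzyme gene of the pathway, was listed at 0 in both libraries and was not used. Of 20 genes for fatty acid synthesis, 17 were lower and 10 of these by at least 2-fold, with a median of −1.03 (−1.26 centred) against 0.01 to 0.51. Fasn, encoding fatty acid synthase, was at 99.6 and 32.2 FPKM, and the elongase gene Elovl6 at 109.6 and 27.6 FPKM. Acss2 was at 30.1 and 7.61 FPKM, Me1 at 20.3 and 6.85 FPKM and the desaturase gene Scd2 at 1228 and 525 FPKM.

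Cell cycle genes were higher in Tsc1cKO without exception among the G2/M and S phase lists. All 40 G2/M and mitosis genes were higher, 24 by at least 2-fold, with a median of 1.03 (0.82 centred) against a random range of 0.02 to 0.32. Kif23, which encodes a kinesin of cytokinesis, was at 3.49 and 13.0 FPKM, Birc5, encoding survivin, at 12.4 and 32.5 FPKM, Ccnb1, encoding cyclin B1, at 5.69 and 15.7 FPKM, Cdk1 at 6.62 and 17.5 FPKM and Ube2c at 15.8 and 34.9 FPKM. All 38 genes of DNA replication and the G1/S transition were higher as well, 12 by at least 2-fold, with a median of 0.84 (0.64 centred) against 0.02 to 0.33. Rrm2, encoding a subunit of ribonucleotide reductase, was at 8.68 and 24.6 FPKM, Pcna, encoding the replication clamp, at 53.5 and 111 FPKM, Chaf1b at 3.65 and 9.89 FPKM, Fen1 at 6.85 and 17.2 FPKM and Gins1 at 2.75 and 7.63 FPKM.

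Of 11 genes for D-type cyclins and G1 kinases, 10 were higher (8 when centred), with a median of 0.50 (0.33 centred). This lay within the random range of −0.13 to 0.53 as deposited and above its own random range when centred. Ccnd1 was at 84.8 and 173 FPKM, Ccnd3 at 45.8 and 142 FPKM, Cdk2 at 10.3 and 30.6 FPKM and Cdk4 at 116 and 261 FPKM. Cell cycle inhibitors and p53 targets went both ways, with 12 higher and 10 lower of 22 and a median of 0.24 (0.03 centred) inside the random range of −0.03 to 0.42. Cdkn1a, which encodes the inhibitor p21, was 3.13-fold lower, at 185 and 59.1 FPKM, and Cdkn1c was at 140.2 and 117 FPKM. Cdkn2b, encoding the inhibitor p15, was at 6.61 and 14.5 FPKM, Bax, which promotes apoptosis, at 59.6 and 135 FPKM and Gdf15 at 0.167 and 1.89 FPKM. Of 17 listed replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, 4 were measured, too few to compare with random lists. Their median was 0.89, with Hist1h4i at 1.77 and 6.56 FPKM. Hist1h2ae, at 0.523 and 1.15 FPKM, was measured only through its Tsc1cKO value.

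Genes of immature and non-myelinating Schwann cells, listed together with negative regulators of myelination, were higher in 14 of 18 cases (13 when centred). Of these, 9 were higher by at least 2-fold. Markers of these cells, chosen after their values were seen, did not move together. Ngfr was higher at 69.5 and 220 FPKM, and L1cam was at 13.2 and 15.6 FPKM. Scn7a was at 18.2 and 17.0 FPKM, Cdh2 at 6.90 and 4.75 FPKM and Gfap at 4.34 and 2.05 FPKM. Their median was 0.88 (0.68 centred), above the random range of −0.03 to 0.47. The median was 0.49 without Sox2, the member with the largest difference (range −0.04 to 0.48), and 0.47 without genes of another list (range −0.05 to 0.47), both at the upper edge. Sox2, which encodes a factor that holds Schwann cells in the immature state, was at 8.76 and 62.5 FPKM, Gap43, encoding a growth-associated protein, at 5.76 and 41.8 FPKM, Egr3 at 9.78 and 62.3 FPKM and Id2, encoding an inhibitor of differentiation, at 55.8 and 209 FPKM. Dhh, encoding the Schwann cell signal desert hedgehog, was at 189.9 and 151 FPKM. Genes of repair Schwann cells, the state seen after nerve injury, were higher in 12 of 14 cases, with a median of 0.97 (0.80 centred) against −0.13 to 0.41, and of 0.41 with a pseudocount of 5 (range −0.07 to 0.22). Besides Ucn2 these included Btc, a growth factor gene, at 0.315 and 6.47 FPKM, Olig1 at 0.785 and 8.26 FPKM and Runx2 at 0.483 and 4.98 FPKM. All of these were below 1 FPKM in control and counted as measured only through Tsc1cKO. The same held for Fgf5, Gdnf, Artn and Lif, chosen after their values were seen, so the share of higher members partly follows from the filter. Cntf, also chosen afterwards and the member with the highest control value, was 3.73-fold lower, at 90.7 and 24.3 FPKM. Immediate early genes, which also respond to dissection, were higher beside these groups in 14 of 15 cases (12 when centred), with a median of 0.83 (0.62 centred) against −0.08 to 0.44. Fos was at 7.86 and 63.1 FPKM, Atf3 at 5.04 and 37.6 FPKM, Junb at 5.80 and 24.9 FPKM and Ier2 at 10.4 and 31.2 FPKM.

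Genes of the lysosome were higher in 28 of 31 cases (26 when centred), 9 by at least 2-fold, with a median of 0.79 (0.56 centred) against a random range of 0.07 to 0.48. Besides Gpnmb these included Cd63, which encodes a tetraspanin of late endosomes, at 309 and 1667 FPKM, and Hexa, which encodes a subunit of beta-hexosaminidase, at 56.1 and 135 FPKM. Genes of ribosome biogenesis were all higher, 30 of 30 as deposited and 29 when centred, with a median of 0.72 (0.49 centred) against 0.02 to 0.38. Myc, which encodes the factor that drives this programme, was at 3.69 and 14.9 FPKM, Gar1 at 10.1 and 24.4 FPKM, Nhp2 at 20.4 and 47.5 FPKM, the fibrillarin gene Fbl at 34.4 and 77.9 FPKM and the nucleophosmin gene Npm1 at 130.1 and 219 FPKM.

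Targets of the stress factor ATF4 and genes of amino acid metabolism were higher in 23 of 29 cases (21 when centred). Asns, encoding asparagine synthetase, was at 2.95 and 8.89 FPKM, Ddit3, encoding the stress factor CHOP, at 10.6 and 29.0 FPKM, Trib3 at 0.593 and 2.08 FPKM, the serine synthesis gene Psph at 18.6 and 35.7 FPKM and Atf4 itself at 99.9 and 124 FPKM. The median of 0.41 lay at the upper edge of the random range of 0.0006 to 0.41, and when centred, at 0.18, inside it.

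Signalling genes of neuregulin, ERBB receptors, PI3K, AKT and mTOR had no common direction, with 19 of 29 higher (11 when centred) and a median of 0.14 that turned to −0.06 when centred, inside the random range of 0.02 to 0.40 as deposited. Ddit4, which encodes an inhibitor of mTORC1, was 5.27-fold higher at 19.3 and 102 FPKM, and Eif4ebp1, encoding a translation repressor that mTORC1 phosphorylates, was at 44.6 and 73.4 FPKM. Akt1 was at 98.1 and 122 FPKM and Irs1 at 8.49 and 4.53 FPKM. Glycolysis genes and targets of HIF1 had a median of 0.20, inside the range of 0.03 to 0.44, which turned to −0.0013 when centred. Members with values far apart were Ldha, encoding lactate dehydrogenase A, at 122 and 281 FPKM, Pfkp at 4.45 and 12.8 FPKM, Aldoc at 7.51 and 0.682 FPKM and Ndrg1, which Schwann cells use in myelin maintenance, at 597 and 329.9 FPKM.

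Nuclear genes of mitochondrial respiration were higher in all 28 cases as deposited and in 25 when centred, but their median of 0.49 (0.26 centred) lay inside the random range of 0.10 to 0.54, though above that of random lists not matched on expression (−0.0036 to 0.38). Ndufa1 was at 75.6 and 159 FPKM, Cox6b1 at 300.4 and 502 FPKM, Ndufa4 at 202 and 334 FPKM and Sdhb at 70.5 and 109.8 FPKM. Chaperone genes of the endoplasmic reticulum were also inside, with a median of 0.34 (0.12 centred) against 0.01 to 0.52, and Sdf2l1 was their member past 2-fold, at 9.74 and 23.8 FPKM. Interferon-stimulated genes had a median of 0.33 (0.13 centred) against −0.17 to 0.45, with Bst2 at 20.9 and 44.3 FPKM. Genes of the pentose phosphate pathway had a median of 0.23 against −0.14 to 0.60, which turned to −0.0003 when centred, with transketolase (Tkt) lower at 142 and 83.4 FPKM.

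**Figure D2:**
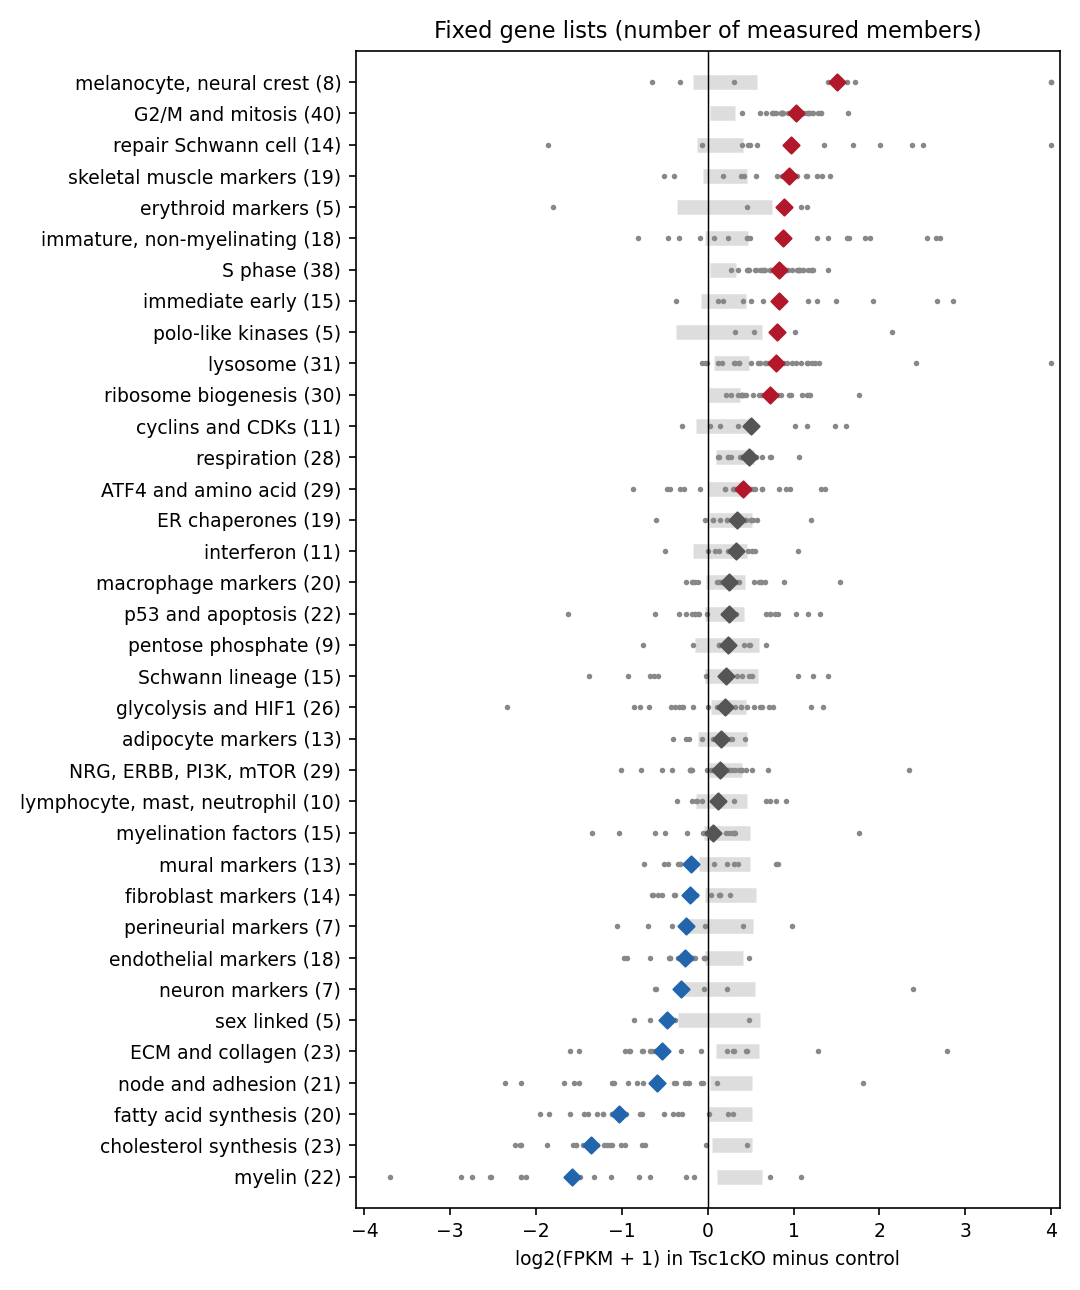
Log2(FPKM + 1) in Tsc1cKO minus control for the members of 36 gene lists, with 1 grey point per gene, diamonds at list medians and grey bars for the central 95% of 10000 random lists matched on expression. Medians above the bars are red (12 lists), below blue (11 lists) and inside dark grey, and 4 points above a difference of 4 are drawn at 4. The myelin list lies lowest at a median of −1.58 and the melanocyte and neural crest list highest at 1.51, values as deposited, and medians of lists near 0 change sign with the scaling. The median of the melanocyte and neural crest list falls between Ednrb and Foxd3, which are also in Schwann cell lists.

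Markers of other cells differed too. Extracellular matrix genes were lower in 16 of 23 cases, with a median of −0.54 (−0.77 centred) against 0.10 to 0.60 and a mean of −0.26. The fibril-associated collagen genes Col12a1 and Col14a1 were at 22.8 and 6.84 FPKM and 106 and 36.9 FPKM, and Sparc was at 4098 and 3878 FPKM. Timp1, which encodes an inhibitor of matrix proteases, was 7.72-fold higher at 6.94 and 53.6 FPKM, and Thbs2 was at 63.8 and 157 FPKM. Fibroblast markers had a median of −0.20 (−0.43 centred) against −0.03 to 0.56, with Serpinf1 at 207 and 133 FPKM and Pdgfra at 23.2 and 15.7 FPKM. Endothelial markers were lower in 17 of 18 cases, with a median of −0.27 (−0.48 centred) against −0.03 to 0.41, and Vwf was at 9.29 and 4.23 FPKM and the VEGF receptor gene Kdr at 11.1 and 5.27 FPKM. Pericyte and smooth muscle markers had a median of −0.19 (−0.42 centred) against −0.11 to 0.49, with Tagln at 51.5 and 30.4 FPKM and Rgs5 at 50.3 and 35.1 FPKM. This list lay inside its random range by its mean (−0.03, range −0.16 to 0.52) and without the filter on low FPKM (median −0.06, range −0.08 to 0.44). Perineurial markers had a median of −0.26 (−0.44 centred) against −0.24 to 0.53, with Cldn1 at 35.1 and 26.0 FPKM, but this list lay inside its random range when centred, with trimmed mean scaling (−0.43, range −0.44 to 0.37), by its mean (−0.15), with a pseudocount of 0.1 (−0.32) and without Msln, its member with the largest difference (−0.15). The 3 lymphatic markers had a median of −0.23, with Reln at 59.5 and 50.6 FPKM.

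Macrophage markers had a median of 0.25 (0.05 centred), inside their random range of −0.02 to 0.43, with C1qc at 75.1 and 116 FPKM and Ctss, a lysosomal protease gene, at 16.1 and 49.0 FPKM. Lymphocyte, mast cell and neutrophil markers had a median of 0.12 against −0.14 to 0.46, which turned to −0.04 when centred, although the mast cell genes Cma1 (8.79 and 17.4 FPKM) and Tpsb2 (9.34 and 16.9 FPKM) were higher. Over the 7 members with at least 5 FPKM the median was 0.68, above the random range of −0.19 to 0.57. Skeletal muscle markers were higher in 17 of 19 cases, with a median of 0.95 (0.75 centred) against −0.06 to 0.46. The fast troponin genes Tnni2 and Tnnt3 were at 38.0 and 104 FPKM and 40.1 and 98.5 FPKM. Adipocyte markers had a median of 0.15 against −0.11 to 0.46, which turned to −0.07 when centred, with Fabp4 at 200.3 and 271 FPKM. Erythroid markers had a median of 0.89 (0.65 centred) against −0.36 to 0.74 over 5 genes, some of them globin paralogs that share reads, with Alas2, the haem synthesis gene of red cell precursors, at 8.83 and 20.9 FPKM. The erythroid list lay inside its random range without the filter on low FPKM (median 0.21 over 11 genes, range −0.11 to 0.27) and by its mean (0.36, range −0.44 to 0.72). Melanocyte and neural crest markers had a median of 1.51 (1.27 centred) against −0.17 to 0.57, with Tyrp1 and Pmel among them, Dct at 0.818 and 4.98 FPKM and Ednrb, encoding an endothelin receptor, at 62.2 and 193 FPKM. The median fell between Ednrb and Foxd3, which also belong to the immature Schwann cell and Schwann lineage lists. Without genes of another list too few members were left to compare, so this median does not speak for melanocyte genes alone.

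Neuron and axon transcripts had a median of −0.31 (−0.45 centred) against −0.28 to 0.55, but a mean of 0.10 inside its own range of −0.33 to 0.62, and the median lay inside its range after centring within classes of transcript length (−0.43, range −0.46 to 0.33), a setting chosen after the data were seen. The neurofilament gene Nefh was at 1.42 and 0.598 FPKM and the intermediate filament gene Prph at 3.70 and 2.73 FPKM, while the tubulin gene Tubb3 was 6.32-fold higher at 3.99 and 25.2 FPKM. Genes that differ by sex had a median of −0.48 (−0.60 centred) against −0.35 to 0.60. The list holds Xist and Y-linked genes, which mark opposite sexes, so this median has no single reading. Xist, which is transcribed from the inactive X chromosome of females, was at 9.28 and 13.3 FPKM, and the Y-linked Ddx3y, Eif2s3y and Kdm5d were at 6.26 and 2.99 FPKM, 9.79 and 5.75 FPKM and 2.05 and 1.19 FPKM, so both libraries held transcripts of both kinds. With Xist higher and these Y-linked genes lower in Tsc1cKO, a different share of each sex in the libraries cannot be told apart from genotype.

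Differences went with transcript length. The median difference was 0.35 in the shortest of 10 equal classes of annotated transcript length and −0.01 in the longest, and the rank correlation across 12036 genes, which are not independent replicates, was −0.23.

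**Figure D3:**
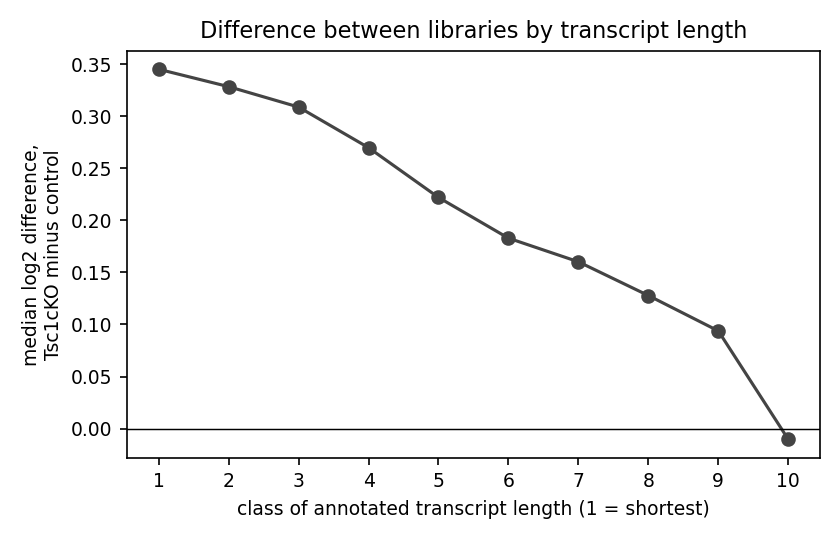
Median log2(FPKM + 1) difference, Tsc1cKO minus control, of measured genes in each of 10 classes of annotated transcript length (horizontal axis, class 1 the shortest), as deposited. The medians lie between 0.35 in the shortest class and −0.01 in the longest, and the position of 0 moves with the scaling.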

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

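The length-centred and failed-value settings were chosen only after the results were seen, and all other settings were planned. Over 17 settings and 65 results, 794 of 841 values counted as unchanged. For genes and lists this means the same side of the threshold or random range, and for counts a change of at most 1.5-fold. Under every setting run on them 27 of 36 lists were unchanged. The results include the 10 largest positive and 10 largest negative differences, which lay far past 2-fold by selection, so the total is no measure of stability. Of these 794 values 770 also kept their sign, and 24 changed it, all of them from 7 lists whose medians lay inside their random ranges. With median scaling these were myelination factors (−0.16), Schwann lineage (−0.02), signalling (−0.06), glycolysis and HIF1 (−0.0013), pentose phosphate (−0.0003), adipocyte (−0.07) and lymphocyte, mast cell and neutrophil genes (−0.04). No paired analysis was possible because each group had 1 library and no test was made. Plk1 fell short of 2-fold with a pseudocount of 5 (0.70), with median (0.79), upper quartile (0.84) and trimmed mean scaling (0.81) and with length centring (0.70), and Plk5 passed it with a pseudocount of 0.1 (2.15). The median of the polo-like kinase list lay inside its random range with a pseudocount of 5 (0.29). Counts of genes higher and lower were 283 and 221 with a pseudocount of 5, 355 and 577 with median scaling, 2211 and 934 at 1.5-fold, and 173 and 134 at 3-fold, where the threshold itself sets the change. The count of higher genes alone also changed by more than 1.5-fold with upper quartile (390) and trimmed mean scaling (363) and with length centring (313). The ATF4 and amino acid list lay inside its random range with pseudocounts of 0.1 (0.43) and 5 (0.30), the filter of 5 FPKM (0.39), median (0.18) and trimmed mean scaling (0.20), the mean (0.36), and without its member with the largest difference (0.39). The list of cyclins and G1 kinases lay above its random range with a pseudocount of 0.1 (0.67), no filter (0.48), the filter of 5 FPKM (1.02), median (0.33), upper quartile (0.37) and trimmed mean scaling (0.34), the mean (0.64), unmatched random lists (0.50) and length centring (0.32). With a pseudocount of 5 other medians outside their random ranges shrank by more than 1.5 times and stayed outside, for G2/M (0.68), S phase (0.52), immediate early (0.55), repair Schwann cell (0.41), sex-linked (−0.19), endothelial (−0.17), neuron (−0.13), perineurial (−0.14) and mural genes (−0.08). With a pseudocount of 0.1 the medians of repair Schwann cell (1.86) and sex-linked genes (−0.74) grew by more than 1.5 times. Medians that changed by more than 1.5 times under at least 1 of the other settings, while staying outside their random ranges, were those of neuron, immature Schwann cell, mural, endothelial, fibroblast, perineurial, ATF4, matrix and melanocyte genes. The list of neuron and axon transcripts reversed when members were averaged, from a median of −0.31 to a mean of 0.10. Apart from the counts at 1.5-fold and 3-fold, the cause was not tested. Of the other values, 23 moved inside a threshold or random range, 12 moved outside one, 1 was the neuron list, which lost its call and changed sign, and 11 were counts that changed by more than 1.5-fold. Settings that dropped low genes gave no value for genes or lists left with too few members, and median, upper quartile and trimmed mean scaling gave none for the polo-like kinase list. Read depth was unknown, so the precision of low values such as those of Plk5 and Tsc1 could not be given.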

Other observations

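The test of the lysosome list against transcript length was set before its result was seen, and all other tests in this part were chosen afterwards, as were the genes named here outside the fixed lists.

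Genes for ribosomal proteins were higher in Tsc1cKO in 75 of 75 cases with a mean of at least 20 FPKM, also under each scaling tried, with a median difference of 0.73 (SD 0.18 across genes) that was 0.39 after centring within 10 classes of transcript length. H2-DMa and H2-DMb1, which encode the chaperone that loads peptides onto MHC class II, were lower, at 92.3 and 13.8 FPKM and 48.4 and 7.26 FPKM, while the class II gene H2-Aa was at 16.3 and 18.1 FPKM and the invariant chain gene Cd74 at 29.7 and 26.2 FPKM. Also lower were Fgf1, which encodes a fibroblast growth factor, at 67.8 and 8.75 FPKM, Tgfa at 11.9 and 0.695 FPKM and Bmp7 at 25.0 and 3.56 FPKM, while the growth factor genes Fgf5, at 0.291 and 3.18 FPKM, and Btc, at 0.315 and 6.47 FPKM, were higher. Growth factor genes were not compared as a list. Single genes with higher values were the acute phase gene Serpina3n at 0.727 and 11.8 FPKM, the laminin gene Lama1 at 0.463 and 10.7 FPKM, the hyaluronan receptor gene Cd44 at 8.92 and 56.3 FPKM, and Gadd45a and Gadd45b, which respond to growth arrest and DNA damage, at 6.37 and 52.2 FPKM and 10.1 and 54.3 FPKM. Differences of these genes other than H2-Aa kept their sign after median scaling, and that of H2-Aa turned from 0.14 to −0.09.

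Tyrp1, Pmel and Gpnmb stood far above control in Tsc1cKO. Melanocytes carried into the nerve sample would bring their other abundant transcripts, but the median of 9 other melanocyte genes in Tsc1cKO was 0.00355% of the Tyrp1 value, and 0.00484% over the 7 genes not listed at 0. Dct, the highest of them, was higher in Tsc1cKO, at 0.818 and 4.98 FPKM, yet reached 0.621% of Tyrp1, which argues against melanocytes as the whole source. The lysosome list without Gpnmb and Cd63, examined for a programme of MiT/TFE factors, had a median of 0.70, but this follows from the list already described and says nothing about Tyrp1 or Pmel. That programme, the genotype and other differences between animals stay open.

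Myelin and lipid synthesis genes were lower together. Fewer Schwann cells in the Tsc1cKO nerve would lower Schwann lineage genes by about as much, but that list had a median of 0.21 against −1.58 for myelin, a gap of 1.79 that exceeded the SD of 0.81 among its members. Its members ranged from −1.39 for Cmtm5 to 1.40 for Foxd3, and the SD is a spread among genes, not an error of the gap. A loss that lowers all Schwann cell genes alike thus does not account for the myelin values, but the list cannot count cells. A trend with transcript length would lose most of the difference on centring, but the medians were then −1.82 for myelin, −1.54 for cholesterol synthesis and −1.19 for fatty acid synthesis. The genotype and other differences between animals stay open, as untested.

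Lysosome genes were higher. Macrophages, which are rich in lysosomes, would raise their other markers by about as much, but 16 macrophage markers that are not lysosomal proteins had a median of 0.25 (SD 0.32) beside 0.79 for the lysosome list. The trend with transcript length does not account for the whole difference, since the median after centring was 0.57. The genotype and other differences between animals stay open, as untested.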
